A study of Mus musculus with 4 samples.

How the data were processed

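Epithelial cells from the small intestine of mice at a neonatal and a juvenile age, each in SPF and GF housing, were sorted by flow cytometry, per the series' design text, and captured in droplets on the Chromium platform, with polyadenylated RNA as the template, per the labels' protocols. The kit is given as a 5′ single-cell kit, so reads start near the 5′ end of transcripts. Cell Ranger 9.0.1 and the genome build GRCm39 are named, per the submitters' processing notes. The settings of cell calling, any later filter on cells and the annotation release are not given in the sources used here. The deposited file names describe the barcodes as those of a filtered matrix, the word Cell Ranger uses for droplets called as cells. How the authors treated doublets is not given in the sources used here.

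For each library 2 text files were used. The first lists the called cell barcodes, each of 16 bases with 1 constant suffix, and the second lists gene IDs, symbols and a feature type. Neither holds a measured value, and per-cell transcript counts were not analysed here. Comparisons of expression between ages or housing conditions, cell type shares and a doublet search, which were planned for the case that counts were among the files, were therefore not made. All lines of the barcode files had the same form, and no barcode occurred more than 1 time within a library. The depth of each library is unknown from these files, and the number of called barcodes stands in its place as the size of the library.

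Groups were taken from the sample titles, with 1 library per group. Ratios of called barcodes have exact 95% intervals from the conditional binomial distribution, single numbers have exact Poisson intervals and shares have exact Clopper-Pearson intervals. They cover counting error only, and those of base shares treat the bases of a barcode as independent draws, which does not hold. No p-value was computed, because cells of 1 library are not replicates. Shared barcodes were found by exact match. Their expected number is the product of the sizes of both libraries divided by the number of barcodes the list allows, which was taken from the segments seen over all 4 libraries. The expected number of first segments unseen in a pair of libraries came from 1000 simulated even draws with a fixed seed. The search for unseen segments was tested on simulated data with 50 segments removed from the P10 libraries among 3840, in 20 repeats. Removed segments are unseen by construction, so this test informs only on the others, of which at most 5 were returned in a repeat. The division of barcodes into segments was found in the data and was not planned.

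Gene symbols were compared with 17 gene lists, fixed before the data were examined, that cover ketone body metabolism, fatty acid oxidation, enterocyte maturation, the epithelial cell types, proliferation, fetal or regenerative epithelium, responses to microbiota and interferon, the circadian clock and cells other than epithelium. Genes are named only as members of these lists, and some members are not reported here. With no counts, a list gives only whether its genes are in the annotation. Gene types were read from GENCODE M21 by gene ID. That release is on another genome build than GRCm39, so no coordinates are given. Alternatives fixed before the data were examined were counting distinct barcodes, leaving out barcodes found in another library or in at least 3 libraries, counting barcodes 1 base apart as shared, and matching symbols without regard to case. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.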

Results

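Single-cell RNA libraries were made from sorted small intestinal epithelial cells of mice. The epithelium of the small intestine is the single layer of absorptive enterocytes, secretory cells and crypt progenitors that lines the gut. The 4 libraries fall into a layout of age by housing. Neonatal mice carried the label P10 and juvenile mice the label P24, read here as postnatal days 10 and 24. At each age 1 library came from mice labelled SPF and 1 from mice labelled GF, the usual abbreviations of specific-pathogen-free and germ-free. The title of the series places ketone body synthesis and the shape-forming program of the neonatal epithelium at the centre of the study. The layout asks how the epithelium differs between the ages, and how it differs between the housing conditions at each age. The values reported here are the barcodes called as cells in each library, the sequences of these barcodes and the genes against which reads were counted. Transcript levels per cell were not analysed here, so no statement on the level of any gene, the share of any cell type or the depth per cell is made. Each group had 1 library, so differences between groups could not be set against the spread between animals, and no test between groups was made.

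A total of 58948 cell barcodes was called over the 4 libraries. The P24 SPF library held 17306 called barcodes (exact 95% Poisson interval 17049 to 17566). The P24 GF library held 13983 (13752 to 14217), the P10 SPF library 13750 (13521 to 13982) and the P10 GF library 13909 (13679 to 14142). These intervals, and the others in this text, cover counting error only and not the variation between animals, sorts or droplet runs.

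**Figure D1:**
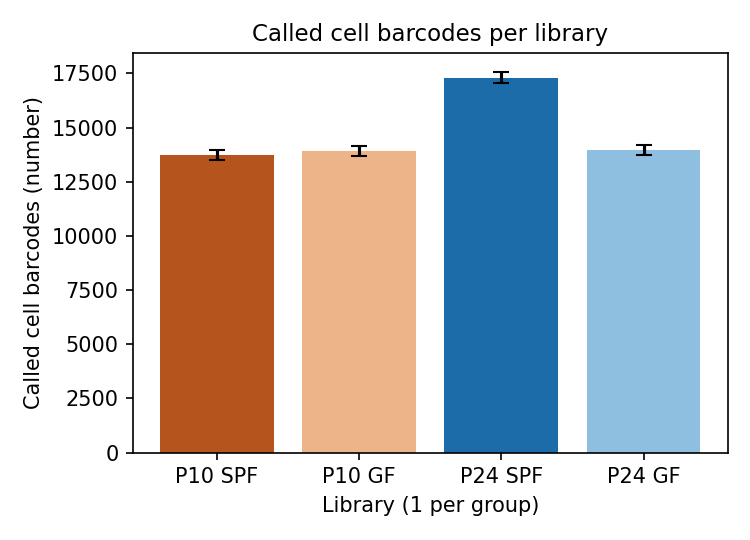
Called cell barcodes (number, vertical axis) in each of the 4 libraries (horizontal axis, 1 library per group). Error bars are exact 95% Poisson intervals, which cover counting error only. The P24 SPF library stands at 17306 and the other 3 lie between 13750 and 13983.

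The age comparison gave a different number of called cells in SPF mice and a like number in GF mice. Within SPF, the P24 library held 1.26 times as many called barcodes as the P10 library (exact 95% interval 1.23 to 1.29, counting error only). Within GF, the ratio of P24 to P10 was 1.01 (0.982 to 1.03). The housing comparison within P24 gave a ratio of SPF to GF of 1.24 (1.21 to 1.27), a difference of 3323 barcodes. Within P10 the ratio of SPF to GF was 0.989 (0.965 to 1.01). The number of called barcodes depends on how many cells were loaded and on how many droplets passed cell calling, so these ratios describe the libraries and not the abundance of epithelial cells in the gut.

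All 4 libraries were counted against the same 33696 genes, listed in the same order. Of these, 31961 (94.9%) had their gene ID in the name table used as reference and 1735 did not. Gene types were read separately from the GENCODE M21 annotation, which lacked 1684 of the IDs. By that release 21409 (63.5% of all) were protein-coding, 5585 were long intergenic RNAs and 2952 were antisense RNAs. The list held 13 genes with symbols starting mt-, which are mitochondrially encoded, and 97 with symbols of Rpl or Rps and a digit. It held 28 with symbols of Defa and a digit, the alpha-defensins, an antimicrobial peptide family of Paneth cells. These numbers rest on symbols alone, so the 97 are not an exact count of ribosomal protein genes. A symbol stood on more than 1 gene ID in 26 cases, and 248 genes had an ID in place of a symbol.

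All 10 members of the list fixed for ketone body synthesis and use were in the annotation common to the 4 libraries, with 1 gene ID each. Among them, Bdh1 (ENSMUSG00000046598) interconverts acetoacetate and beta-hydroxybutyrate, and Oxct1 (ENSMUSG00000022186) is the enzyme with which tissues use ketone bodies. The 19 genes of fatty acid oxidation and PPAR targets were also present, including Cpt1a (ENSMUSG00000024900), which admits long-chain fatty acids to mitochondria, and Ppara (ENSMUSG00000022383), the nuclear receptor that controls many genes of this pathway.

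The lists fixed for suckling-type and adult-type enterocytes were in the annotation as well, though whether each member marks the change between them was not examined. The 15 suckling-type enterocyte genes were present, among them Lct (ENSMUSG00000026354), which encodes lactase. The 13 adult-type enterocyte genes were present, among them Sis, which encodes sucrase-isomaltase. The 9 stem cell genes, which include Lgr5 and Olfm4, the 10 genes of fetal or regenerative epithelium, which include Ly6a and Clu, and the 12 proliferation genes, which include Mki67, were each complete. So were the lists for Paneth cells (8 genes), goblet cells (9 genes), enteroendocrine cells (11 genes) and tuft cells (8 genes). The 18 genes of the list for responses to the microbiota, such as Reg3g, and the 10 interferon response genes were complete too. The list for the microbiota covers antimicrobial defence and antigen presentation, and also holds Retsat and Angptl4. The lists for cells that a sort of epithelium should exclude were complete at 11 immune genes, 11 stromal, endothelial, muscle and glial genes and 5 red blood cell genes. Of the 7 circadian genes 6 were found by symbol. The exception, Bmal1, which encodes a core clock transcription factor, was listed under its older symbol Arntl (ENSMUSG00000055116). In total 184 of 185 symbols were found, each on 1 gene ID. Angptl4, which stands in more than 1 list, was counted 1 time. Presence in this list shows that a gene could receive counts and says nothing on whether it was expressed. Alpha-defensins, Saa1 and Saa2, and Hba-a1 and Hba-a2 are related genes listed separately, so reads that match more than 1 of them could be dropped in the counting. Their sequences were not compared here.

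Barcodes that occur in more than 1 library did not exceed chance by more than counting error. The 6 pairs of libraries shared 372 barcodes in sum (exact 95% Poisson interval 335 to 412), against 352 expected by chance from the size of the barcode list. The expected number lay inside the interval of the observed number in 6 of 6 pairs, and the observed number was 0.960 to 1.18 times the expected one. The same list size was used for every pair, although both P10 libraries held no barcode on 96 first segments described below. The expected number for P10 SPF and P10 GF, 51.9 against 61 shared, is therefore somewhat too low. Of the 58578 distinct barcodes 366 occurred in 2 libraries, 2 in 3 libraries and 0 in all 4. Barcodes also found in another library made up 1.13% of those called in P24 SPF, 1.26% in P24 GF, 1.32% in P10 SPF and 1.32% in P10 GF.

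The called barcodes were built from parts, and the first segments with 1 linker differed between the ages. Each barcode of 16 bases had a first segment at positions 1 to 7, a pair of linker bases at positions 8 and 9 and a second segment at positions 10 to 16, counted from the 5′ end. Over all libraries 4 linkers occurred, each with its own 960 first and 960 second segments, so that the list seen here allows 3686400 barcodes. Barcodes with the linker TC made up 25.7% of those called in P24 SPF (exact 95% interval 25.0% to 26.3%) and 25.3% in P24 GF (24.6% to 26.0%). In P10 SPF they made up 22.8% (22.1% to 23.5%) and in P10 GF 22.7% (22.0% to 23.4%), and the intervals of the P10 libraries did not reach those of the P24 libraries. Of the 3840 first segments, 98 were seen in neither P10 library, and 96 of these had the linker TC. The highest number in 1000 simulated even draws of the same size was 9. The same 96 segments carried 431 called barcodes in P24 SPF and 345 in P24 GF, against 433 and 350 expected from an even draw. The pair of P24 libraries lacked 2 first segments in common. Between ages, a pair of libraries lacked 2 to 6 in common. Second segments showed no such gap, with 3 unseen in both P10 libraries, 4 unseen in both P24 libraries and 0 to 4 unseen in a pair of different ages. Over all barcode positions, G made up 24.5% of bases in P24 SPF (exact 95% interval 24.3% to 24.7%) and 24.9% in P10 SPF (24.8% to 25.1%), and C made up 26.5% (26.3% to 26.6%) and 26.1% (25.9% to 26.3%), with intervals that did not meet. In the GF libraries G made up 24.5% at P24 and 24.8% at P10, and C made up 26.4% and 26.3%, with intervals that overlapped. A and T had overlapping intervals in all 4 libraries, with A between 25.7% and 25.8% and T between 23.2% and 23.3%. The intervals of base shares treat the bases of a barcode as independent draws, which does not hold. Whether such intervals meet therefore does not decide a difference. The linker bases count among the positions, so the lower share of TC barcodes in the P10 libraries enters the base shares too. Base shares without the linker bases were not computed.

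**Figure D2:**
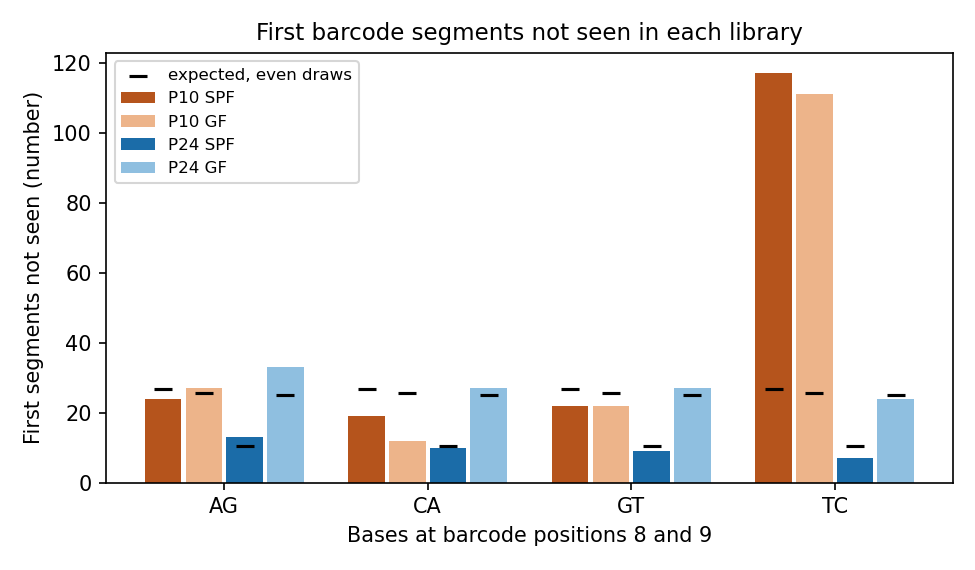
First barcode segments not seen in each library (number, vertical axis) by the bases at barcode positions 8 and 9 (horizontal axis), with 1 bar per library; black dashes give the number expected if barcodes were drawn evenly. With the linker TC, 117 segments were unseen in P10 SPF and 111 in P10 GF, against 7 in P24 SPF and 24 in P24 GF.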

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

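The tests on barcode segments, and the use of shared barcodes as a test of carry-over, were chosen after the results were seen, while the ratios of called barcodes and the search for shared barcodes were planned. Barcodes of the P10 libraries lacked a set of first segments that the P24 libraries held. This signal lies in the barcode sequences, outside the comparison of called cells. Of 3840 first segments 98 were unseen in both P10 SPF and P10 GF, and 96 of them belonged to the linker TC. Even draws of beads reached at most 9 in 1000 simulations, which argues against chance. Library size does not account for it, since P24 GF, with 13983 called barcodes against 13909 in P10 GF, held 93 of the 96 segments. Segments were defined from all 4 libraries, so any unseen in both P10 libraries had to occur in at least 1 P24 library. That P24 SPF held 95 of the 96 and P24 GF 93 was not fixed by this. An even loss of barcodes with this linker, as misreading of positions 8 and 9 would give, is argued against too: when the 3138 and 3152 TC barcodes of the P10 libraries were spread evenly over all 960 TC segments, at most 6 segments stayed unseen in both over 1000 simulations.

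A candidate explanation that stays open is that the P10 libraries were made with another batch of barcoded beads, or read against another barcode list, than the P24 libraries. Within linker classes the remaining segments gave no further sign of it. Their numbers in the P10 libraries, less the mean of each class, correlated at r = -0.0030 across 3742 segments (segments are not independent replicates). This lay at percentile 42.3 of 10000 shuffles. Of the 6 pairs of libraries, 1 lay outside the central 95% of its shuffles. It was a pair of different ages, P24 GF and P10 SPF, at r = 0.038 and percentile 99.0. A split by age does not predict this, but each of the 6 pairs was set against its own range with no allowance for their number. That pair therefore does not count against a batch split by age. A batch even in all other segments would show no correlation in the P10 pair either, so the explanation stays open. The labels name no bead batch, and no biological explanation was tested. Age parts these libraries in the same way, but the barcodes are sequences carried by the beads and not by the cells. If a batch is the source, it coincides with age in all 4 libraries, so a comparison of P10 with P24 cannot be told apart from it. Whether the P24 libraries share a batch with each other is not shown by the lack of this deficit.

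The ratio of called barcodes between SPF and GF lay above 1 at P24 and below 1 at P10, which is why it appears here. It was 1.24 at P24 and 0.989 at P10, a quotient of 1.25. The difference was not tested, and the interval at P10, 0.965 to 1.01, includes a ratio of 1. Barcodes carried over from the other libraries do not account for the excess of 3323 barcodes in P24 SPF over P24 GF, since only 196 barcodes of P24 SPF occurred in any other library. The title of the P24 SPF library is the only one of the 4 that carries a date, whose meaning the labels do not give, so a separate processing day for this library is open. The number of cells loaded and a looser cell call were not tested.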

How the results depend on the processing

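Of the 45 values recomputed under alternatives fixed before the data were examined, 14 could not move. Counting distinct barcodes gave 8 of these, since no barcode occurred again within a library, and counting barcodes 1 base apart as shared gave 6, since no segments of a linker class differed at 1 base. The other 31 lay inside the 95% interval of the value as reported or, for the gene lists, within 1.5 times it. They had little room to leave it. Only 2 barcodes occurred in 3 libraries, and barcodes also found in another library made up 1.13% to 1.32% of a library. With 184 of 185 symbols found, matching without regard to case could not pass the tolerance. Without barcodes also found in another library, the ratio of P24 to P10 was 1.26 in SPF and 1.01 in GF, and the ratio of SPF to GF was 1.24 at P24 and 0.989 at P10. Matching symbols without regard to case moved nothing. The alternatives for linkers and segments were chosen after seeing the data. Leaving out the first segments unseen in both P10 libraries lowered the share of TC barcodes to 23.8% in P24 SPF and 23.4% in P24 GF, which follows from the construction, beside 22.8% in P10 SPF and 22.7% in P10 GF. Without barcodes found in another library the number of first segments unseen in both P10 libraries was 98, and by construction it could not fall. The alternatives planned for expression, a filter on cells by transcript number and mitochondrial share and a total without abundant gene classes, were not run, because per-cell counts were not analysed here. With 1 library per group no library could be left out.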
